A study of Homo sapiens with 9 samples.

How the data were processed

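RNA from 9 human cancer cell lines was hybridised to Affymetrix whole-genome 3' expression arrays, with 1 array per line. Per the labels' protocols, RNA was isolated with a column kit and biotin-labelled by the standard Affymetrix protocol. The labels class 5 lines as aggressive and 4 as non-aggressive, in 4 sets by tumour type. The breast set holds MCF7 (non-aggressive) and 231MFP (aggressive). The ovarian set holds OVCAR3 (non-aggressive) and SKOV3 (aggressive), and the melanoma set holds MUM2C (non-aggressive) and C8161 (aggressive). The prostate set holds LNCaP (non-aggressive) with DU145 and PC3 (both aggressive). The submitters compared lines only within a set and stated that normalization differed between the sets, so the comparisons of class, lists and pairs used differences within a set. Levels of different sets were also set against each other in the alternative without the set block, in the test for cells of another line in the C8161 culture and in the description of genes near 0 in a line. The 3' to 5' ratios were also compared over arrays of different sets. Bounds on the scaled signal, as for the fibroblast genes, were the same for all sets in spite of the difference in normalization. No line had a second array. The spread in every test is therefore the spread between lines, and the number of arrays limits the precision.

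The deposited values of the breast, ovarian and melanoma arrays were linear intensity values, made with MAS5 per the submitters' processing notes. Each of these arrays had been brought by the authors to the same 2% trimmed mean, between 250.035 (MCF7) and 250.043 (C8161). The deposited values of the prostate arrays were log2 values, made with RMA per the same notes, with maxima from 14.66 to 14.70. The versions of MAS5 and RMA were not given in the sources used here. RMA adjusts the background and brings arrays run together to a common distribution, whereas MAS5 scales each array on its own. Small signals are therefore spread more widely in the MAS5 sets than in the prostate set. Detection calls were not used here.

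The log2 columns were returned to a linear scale and each array was scaled to a 2% trimmed mean of 500. This value is called the scaled signal, in arbitrary units. Then 50 was added and the log2 taken. Folds and log2 differences are on this log2(signal + 50) scale, which understates the change of dim genes and keeps noise near 0 small. The table held 54675 probe sets. By the platform annotation given, 41097 had 1 gene symbol, 1801 had several and 11777 had none. Only probe sets with 1 gene were used, and 41043 of them matched the gene table by Entrez identifier, with 0 symbols changed. Each of 19740 genes was represented by the probe set with the highest mean log2 value over the 9 arrays. Genes on the Y chromosome and XIST were left out. Genes with a scaled signal of at least 200 on at least 2 of the 9 arrays were tested, 12137 in all. The share of probe sets at a scaled signal of 200 or more ran from 29.5% (SKOV3) to 34.7% (OVCAR3) on the MAS5 arrays and from 39.0% (PC3) to 39.6% (DU145) on the RMA arrays. No genomic coordinates are given, because the sources used here name no genome build.

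The comparison of aggressive with non-aggressive lines across the sets used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with the set as a block. The fit left 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Within a set, genes with a scaled signal of at least 200 on the higher array were counted at 4-fold or more. Such differences between 2 arrays have no replicate check and carry no p-value. Genes at least 2-fold different in the same direction in all 5 pairs of lines were counted likewise. DU145 and PC3 shared LNCaP as their partner, so these 2 differences are not independent.

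There were 27 gene lists, of which 26 had at least 5 tested members. Lists were tested across the sets with camera (limma) at a preset correlation of 0.01, and again with the correlation estimated from the data. Benjamini-Hochberg adjustment ran over the 26 lists. An exact permutation test of each list's mean difference used the 24 assignments of class within the sets and was two-sided. Its smallest possible p is 0.0417, and the 5 lists at that value had 0.217 after adjustment over the 26 lists. Within a pair, a list's median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of those arrays. Of 677 list entries, 47 had no single-gene probe set in the annotation given and were not analysed here. The lists of immune cells and of endothelial and blood cells, which these cultures should not hold, and of housekeeping genes served as controls.

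Genes named in the text followed a rule. Across the sets it took up to 10 genes in each direction past the adjusted threshold by size. Where fewer than 5 passed in a direction, it took the 5 of smallest p. It also took the 10 genes in each direction with the largest smallest difference over the 5 pairs. Within each set it took the 8 genes in each direction with the largest difference among genes whose higher array reached 1000. In the prostate set these were ranked by the smaller of the 2 differences. In each list it took the members with the 2 largest differences each way. MGLL, NCEH1, FASN, CDH1, VIM, CD44 and CD24 were always named. Named genes outside the lists had no other bright probe set whose mean difference over the pairs had the opposite sign. SLCO1B3, CDA, IGFBP6, NCEH1 and ZNF595 had no other bright probe set at all, so this check could not bear on them. For a gene named in a single pair, the check used the mean over the pairs and not that pair. The tests of the comparisons, the lists, the naming rule and the alternatives were fixed before the data were examined. Some tests of explanations in the closing section were chosen later.

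The fit was tested on simulated data for the comparison across the sets, with 200 of 12137 genes changed in each of 20 runs. It recovered 1.5% of genes changed 2-fold, 47% of those changed 4-fold, 89.5% at 8-fold and 97.9% at 16-fold. False genes made up 6% of the calls. The noise was drawn as normal with the fitted spread of each gene, and 200 genes were changed. The shares recovered therefore need not hold for the data. There 7 genes passed, and AXL, higher by 5.65 on the log2 scale or over 16-fold, did not. Alternatives were other pseudocounts (16 and 200), a floor of 100 in place of the pseudocount, the values as deposited without scaling of each array, and quantile normalization within the sets or of all arrays. Further alternatives were no filter, a stricter filter of 500, the mean of all probe sets of a gene, no set block, 1 difference per set, a trended and robust prior, and leaving out each line in turn. Leaving out either line of a pair removes that set's difference from the fit.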

Results

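Transcript levels were measured in 9 established human cancer cell lines on 1 array each. The series asked how aggressive lines differ from non-aggressive lines of the same tumour type. The aggressive lines were 231MFP (breast), SKOV3 (ovarian), C8161 (melanoma), and DU145 and PC3 (prostate), n = 5. Their non-aggressive partners were MCF7, OVCAR3, MUM2C and LNCaP, n = 4. MCF7 is an oestrogen receptor-positive breast line and LNCaP an androgen-responsive prostate line. Per the labels, the ovarian pair and the melanoma pair each grew in a shared medium, whereas the lines of the breast and the prostate set differed in medium. The breast, ovarian and melanoma arrays held linear MAS5 intensities and the prostate arrays log2 RMA values, so differences were taken within a set unless stated. The ratio of the 3' to the 5' probe set of beta-actin, a measure of RNA integrity, was 3.58 on the C8161 array and between 0.945 and 1.34 on the other 8 arrays. The same ratio for GAPDH was 1.79 on the C8161 array and between 0.877 and 1.03 on the others.

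The first comparison asked which genes separated the classes across all 4 sets. SLCO1B3, an organic anion transporter, rose by 5.03 ± 0.33 on the log2 scale (SE of the limma fit, 5 aggressive and 4 non-aggressive lines, adjusted p = 0.0084). CDA, which deaminates cytidine, rose by 4.80 ± 0.47 (adjusted p = 0.0377). LOXL2, a lysyl oxidase that cross-links collagen, rose by 4.55 ± 0.49 (adjusted p = 0.0467). ZEB1, a transcription factor that represses epithelial genes, rose by 4.46 ± 0.44 (adjusted p = 0.0377). IGFBP6, which binds insulin-like growth factors, rose by 3.51 ± 0.39 (adjusted p = 0.0467). NCEH1, a neutral cholesterol ester hydrolase, rose by 3.36 ± 0.35 (adjusted p = 0.0397). ZNF595, a zinc finger gene of a family with similar members that a probe set can share, was the only gene to pass in the other direction, at -5.09 ± 0.42 (adjusted p = 0.0224). These 7 of 12137 genes passed the adjusted threshold of limma, 6 higher and 1 lower in the aggressive lines. At an unadjusted p under 0.05 there were 683 genes higher and 659 lower.

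Each of the 7 genes moved the same way in all 5 pairs. The scaled signal of SLCO1B3 was 31.7 or less in the 4 non-aggressive lines and between 1419 (231MFP) and 2937 (C8161) in the 5 aggressive lines. ZNF595 showed the opposite, with 59.7 or less in the aggressive lines and between 1571 (OVCAR3) and 6000 (MUM2C) in their partners. NCEH1 lay 8.08-fold higher in 231MFP, 9.36-fold in SKOV3, 9.96-fold in C8161, 19.8-fold in DU145 and 9.36-fold in PC3 than in the partner line. The calls rested on few lines. Without the breast pair, without LNCaP or without DU145 0 genes passed in limma, with 1012, 1194 and 1080 genes at an unadjusted p under 0.05. By contrast, 4 passed without the ovarian pair, 2 without the melanoma pair and 2 without PC3. Of the 7 genes, these held SLCO1B3 and ZNF595 without the ovarian pair, SLCO1B3 alone without the melanoma pair, and CDA and SLCO1B3 without PC3. Other settings gave between 1 gene (no filter on dim genes) and 13 genes (no set block).

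Among genes that did not pass, RHOB, a small GTPase, was the nearest on the lower side (-2.22 ± 0.31, adjusted p = 0.0908), followed by GRTP1 (-2.59 ± 0.37, adjusted p = 0.0918), the receptor ERBB3 (-4.78 ± 0.74, adjusted p = 0.126) and the phosphatase DUSP16 (-1.90 ± 0.30, adjusted p = 0.128). MGLL, the monoacylglycerol lipase that releases fatty acids from monoacylglycerols, was 2.99 ± 0.52 higher and did not pass (adjusted p = 0.174). It was nevertheless higher in each aggressive line, by 3.43-fold in 231MFP, 7.56-fold in SKOV3, 28-fold in C8161, 9.21-fold in DU145 and 3.90-fold in PC3. The intermediate filament gene VIM (4.27 ± 0.95, adjusted p = 0.234) and the hyaluronan receptor CD44 (3.22 ± 0.75, adjusted p = 0.258) were also higher in all 5 pairs without passing. E-cadherin, CDH1 (-2.37 ± 1.10, adjusted p = 0.476), the fatty acid synthase FASN (-0.45 ± 0.51, adjusted p = 0.800) and CD24 (0.68 ± 1.37, adjusted p = 0.899) went in different directions in different pairs.

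**Figure D1:**
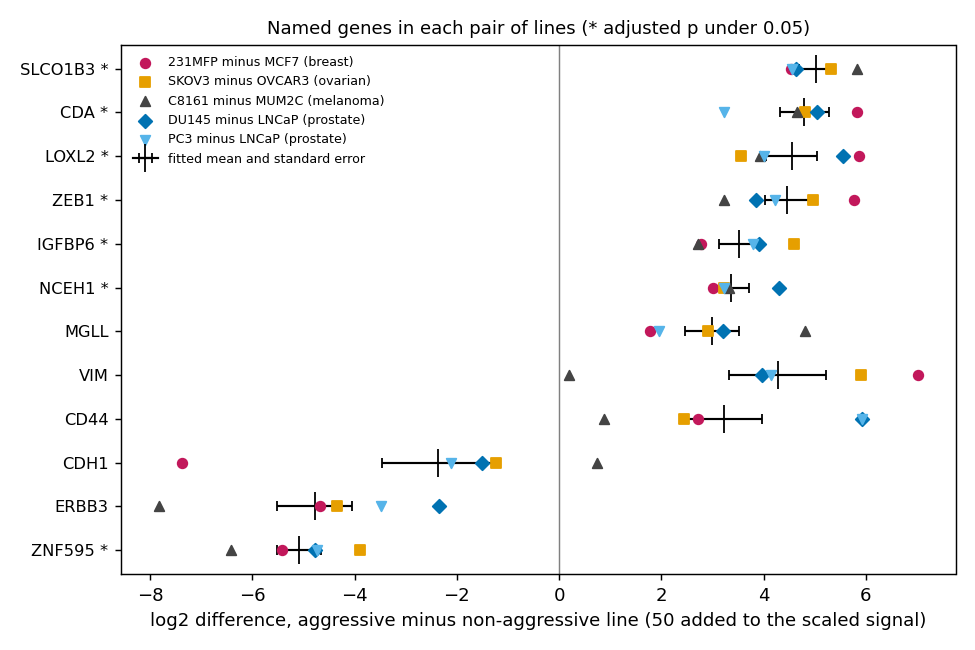
Log2 difference (aggressive minus non-aggressive line, with 50 added to the scaled signal) of 12 named genes in each of the 5 pairs, where each coloured symbol is 1 pair, the black tick is the mean of the limma fit and the bar is its standard error. SLCO1B3 lies between 4.53 and 5.83 and ZNF595 between -6.42 and -3.89 in the 5 pairs, whereas VIM is at 0.20 and CDH1 at 0.74 in the melanoma pair.

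Counting by size, 74 genes were at least 2-fold higher and 22 at least 2-fold lower in the aggressive line of all 5 pairs. All 7 genes that passed the test were among them. The receptor tyrosine kinase AXL was higher by 276-fold in 231MFP, 11.8-fold in SKOV3, 25.7-fold in C8161, 98.0-fold in DU145 and 47.9-fold in PC3 (5.65 ± 0.68, adjusted p = 0.0745). G0S2, an inhibitor of triglyceride lipolysis, was at least 8.39-fold higher in each pair. The cell adhesion gene CLMP was at least 6.92-fold higher, and the lysophosphatidic acid receptor LPAR1 at least 5.82-fold higher. None of these 4 passed the test across the sets. On the lower side, ERBB3 was at least 5.09-fold lower in each pair, with a scaled signal of 12790 in MUM2C and 6.71 in C8161. GRTP1 was at least 3.74-fold lower and RHOB at least 3.58-fold lower. SETBP1, FHDC1, KIF5C and DUSP16 were each at least 3.12-fold lower, and PHGDH, which starts serine synthesis, at least 2.67-fold lower. The homeobox gene IRX3 was at least 2.54-fold lower. With 1 array per line, a difference within a pair has no replicate check. The lower genes numbered 38 with a pseudocount of 16 and 10 with 200, and the higher genes 39 when all probe sets of a gene were averaged.

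**Figure D2:**
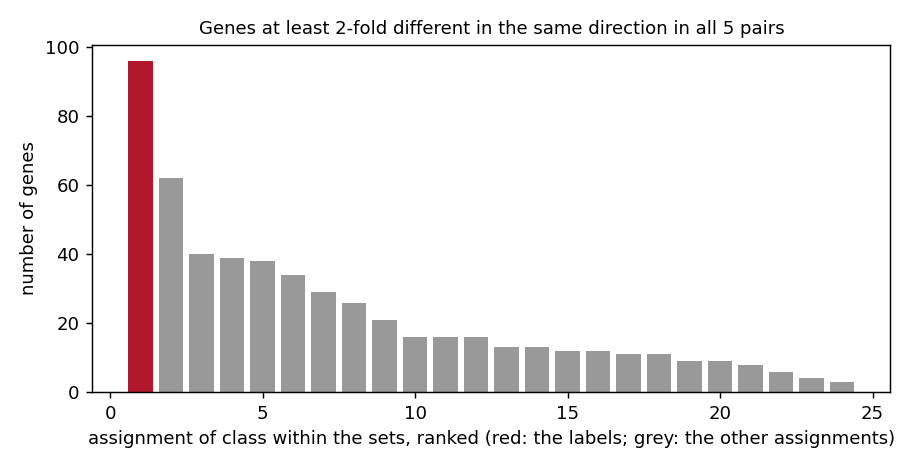
Number of genes at least 2-fold different in the same direction in all 5 pairs (vertical axis) under each of the 24 assignments of class within the sets, ranked from left to right, with the labelled assignment in red. The labelled assignment gives 96 genes and the highest of the others gives 62.

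The gene lists asked which programmes moved with the class. Of 33 tested mesenchymal genes, 32 were higher in the aggressive lines, by a mean of 2.18 on the log2 scale (camera, adjusted p = 1.7e-15). With an estimated correlation the list did not pass (adjusted p = 0.10), and the exact permutation p was 0.0417, the smallest the 24 assignments can give, or 0.217 adjusted over the lists. Of its members 2 passed over all genes tested and 9 when adjusted over the list alone. AXL and LOXL2 had the largest differences, whereas the collagen gene COL1A1 (-0.51 ± 0.98) and the actin-binding CALD1 (0.07 ± 1.10) had the smallest. The median of the list was 3.11 higher in 231MFP, 1.37 in SKOV3, 1.67 in C8161, 2.02 in DU145 and 2.39 in PC3, above all 10000 random lists in each pair. The beta-actin 3' to 5' ratio also differed within pairs, by 0.14, 0.47, 1.66, -0.05 and -0.17 on the log2 scale in the same order.

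Of 38 tested epithelial genes, 30 were lower in the aggressive lines, by a mean of -1.11 (camera, adjusted p = 5.7e-06). The list did not pass with an estimated correlation (adjusted p = 0.518), and its exact permutation p was 0.25. Adjusted over the list alone, 1 member passed (ERBB3), and 0 passed over all genes tested. The largest differences were those of ERBB3 and of the small GTPase RAB25 (-4.21 ± 1.03) on the lower side, and of the keratins KRT7 (3.71 ± 1.38) and KRT19 (1.53 ± 1.10) on the higher side. The list's median was lower in 231MFP (-3.06), SKOV3 (-1.20), DU145 (-0.87) and PC3 (-0.75) but higher in C8161 (0.69), the line with the 3' to 5' ratio of 3.58, than in the partner line. The C8161 median rested largely on dim genes, being 0.23 with a pseudocount of 200 and 0.03 with a floor of 100. In the breast pair 36 of the 38 genes were at least 2-fold lower, and in the melanoma pair 15 were at least 2-fold higher and 5 lower.

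Of 13 tested stem and progenitor markers, 8 were higher, by a mean of 0.67 over the list (camera, adjusted p = 0.0271; adjusted p = 0.42 with an estimated correlation; exact permutation p = 0.125). Adjusted over the list alone 4 members passed on the higher side and 1 on the lower side, and 0 passed over all genes tested. The ecto-nucleotidase NT5E (3.30 ± 0.83) and CD44 were highest, and the transcription factors SOX2 (-2.74 ± 0.82) and MYC (-0.47 ± 0.68) lowest. Judged by the unadjusted camera p, the call was lost without LNCaP (mean 0.32) and without the filter on dim genes (mean 0.33).

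Lipid metabolism was covered by several lists. In the list of the endocannabinoid and monoacylglycerol pathway 5 of 13 tested genes were higher, and the list did not pass (camera, adjusted p = 0.847). Its mean was 0.06, its median -0.26 and the test's direction was down. MGLL (2.99 ± 0.52) passed when adjusted over the list alone, whereas no gene of the list passed over all genes tested. The fatty acid-binding FABP5 was 2.38 ± 0.93 higher, PLCB1 was at -2.42 ± 0.68 and the amidase gene FAAH2 at -0.96 ± 0.41. Of 17 tested genes of lipolysis and fatty acid release 14 were higher, with a mean of 0.66 (camera, adjusted p = 0.0023). The middle gene of this list by size, PNPLA2, was at 0.27 ± 0.43. With an estimated correlation adjusted p was 0.265, and the exact permutation p was 0.0417. NCEH1 and MGLL passed over the list alone and had its largest differences, and NCEH1 alone passed over all genes tested. PLA2G6 (-0.57 ± 0.38) and the lipid droplet coat gene PLIN2 (-0.28 ± 1.41) had the lowest.

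Of 24 tested genes of fatty acid oxidation 20 were lower, with a mean of -0.46 (camera, adjusted p = 0.0070). The adjusted p was 0.332 with an estimated correlation, and the exact permutation p was 0.0417. No member passed over all genes or over the list alone. ECI1 (-1.39 ± 0.41) and ACAA2 (-1.37 ± 0.94) were lowest, and ACOX2 (0.74 ± 0.43) and ECI2 (0.67 ± 0.64) highest. De novo fatty acid synthesis did not pass (camera, adjusted p = 0.464), with 13 of 18 genes lower. Its regulator SREBF1 was at -1.55 ± 0.45 and ELOVL7 at -1.43 ± 0.89, and the acyl-CoA synthetases ACSL5 (2.03 ± 0.79) and ACSL4 (1.63 ± 0.73) lay highest. Ether lipid synthesis (adjusted p = 0.655, 14 genes) and lysophosphatidic acid and prostaglandin signalling (adjusted p = 0.847, 17 genes) did not pass by camera. Their means were 0.11 and 0.13 and their medians -0.33 and -0.21. Of their members, NCEH1 passed in the former and LPAR1 in the latter when adjusted over the list alone. In the former list AGPS was at 1.07 ± 0.59, PAFAH1B3 at -0.80 ± 0.68 and PAFAH2 at -0.79 ± 0.40. In the latter PTGIS was at 1.28 ± 0.70, LPAR2 at -1.29 ± 0.69 and PLPP2 at -1.29 ± 0.73.

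**Figure D3:**
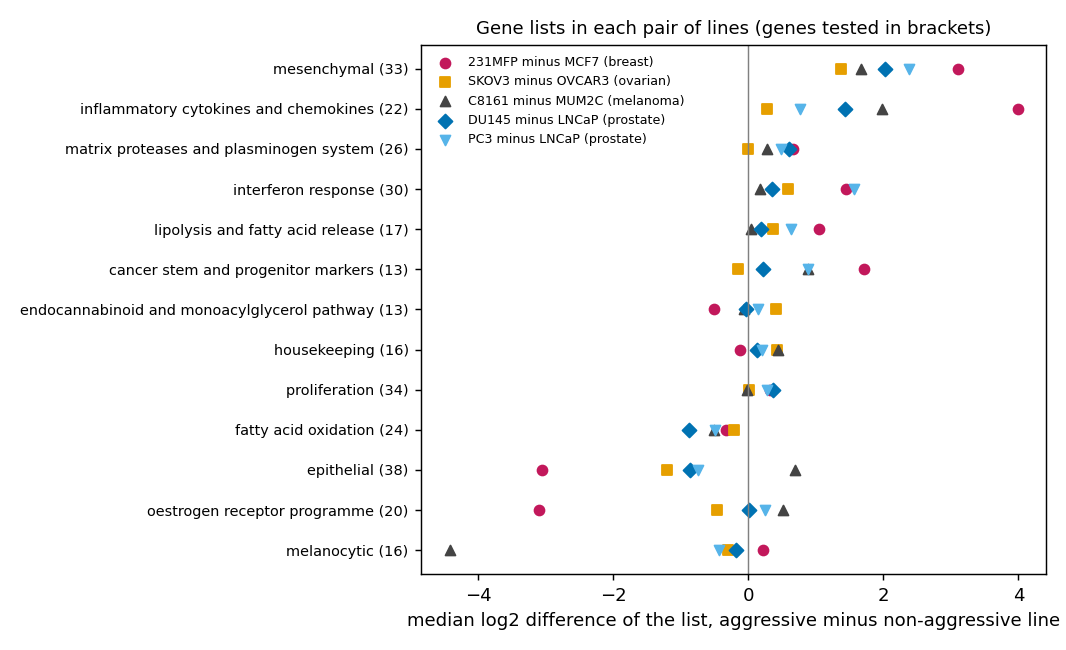
Median log2 difference (aggressive minus non-aggressive line) of 13 gene lists in each of the 5 pairs, where each symbol is 1 pair and the number of tested genes stands in brackets. The mesenchymal medians lie between 1.37 and 3.11, whereas the epithelial median is 0.69 in the melanoma pair and between -3.06 and -0.75 in the others.

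Of 22 tested inflammatory cytokine and chemokine genes 21 were higher in the aggressive lines, with a mean of 1.91 (camera, adjusted p = 7.8e-10). With an estimated correlation the list did not pass (adjusted p = 0.318), and the exact permutation p was 0.0417. Adjusted over the list alone 12 members passed on the higher side and 1 on the lower side, and 0 passed over all genes tested. The neutrophil-attracting chemokines CXCL8 (5.23 ± 0.97) and CXCL1 (5.0 ± 1.07) were highest, and CXCL16 (-1.34 ± 0.33) and TNF (0.03 ± 0.32) lowest. The median was 4.0 higher in 231MFP and 1.98 in C8161, but 0.28 in SKOV3. Of 26 matrix protease and plasminogen genes 18 were higher, with a mean of 0.90 (camera, adjusted p = 0.00092; adjusted p = 0.318 with an estimated correlation; exact permutation p = 0.0417). Adjusted over the list alone 3 passed, all higher, and 0 passed over all genes tested. The urokinase gene PLAU was 4.84 ± 1.10 higher and the collagenase gene MMP1 3.59 ± 1.33 higher, whereas MMP9 (-0.95 ± 0.46) and MMP15 (-0.91 ± 0.28) were lowest.

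Of 30 interferon response genes 25 were higher, with a mean of 0.94 (camera, adjusted p = 1.0e-06; adjusted p = 0.318 with an estimated correlation; exact permutation p = 0.0833). No member passed over all genes or over the list alone. IFIT3 (2.58 ± 0.82) and PSMB8 (2.36 ± 0.93) were highest, and MX2 (-0.44 ± 0.46) and IFI6 (-0.41 ± 0.59) lowest. Receptor tyrosine kinases and their ligands divided into 14 higher and 13 lower genes, with a mean of 0.61 (camera, adjusted p = 0.0385; adjusted p = 0.42 with an estimated correlation; exact permutation p = 0.0833). Adjusted over the list alone 5 passed on the higher side and 1 on the lower side, and 0 passed over all genes tested. AXL and the growth factor PDGFC (3.92 ± 0.74) were highest, and ERBB3 and ERBB4 (-1.76 ± 0.80) lowest. The housekeeping list (adjusted p = 0.109, 16 genes), the proliferation list (adjusted p = 0.192, 34 genes) and the endothelial and blood cell list (adjusted p = 0.213, 5 genes) did not pass by camera. Of 18 immune cell genes 2 were bright enough to test, so that list was not tested. CD19 and CD68 had no single-gene probe set, and the others were too dim.

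The remaining comparisons were within the sets, as the submitters intended, and describe 2 or 3 arrays each. In the breast pair 918 genes were at least 4-fold higher and 793 at least 4-fold lower in 231MFP than in MCF7, of 10936. With a pseudocount of 200 these were 511 and 405, and the counts of the other pairs were smaller too. Higher in 231MFP were CXCL8 (460-fold, with a scaled signal of 9.7 in MCF7), the cystatin gene CST1 (432-fold, with 7.2 in MCF7), MMP1 (388-fold), IGFBP7 (323-fold), SPANXB1 (322-fold), AXL, the glutathione peroxidase gene GPX1 (250-fold, with a scaled signal of 10.5 in MCF7) and the actin-bundling PLS3 (187-fold). The order depends on the value added to the signal. On the log2 scale CXCL8 was at 10.06 with a pseudocount of 16 and 7.04 with 200, whereas MMP1 was at 9.22 and 7.25. The CXCL8 probe set and that of SPANXB1, a family of near-identical genes, can share signal with related transcripts. Lower in 231MFP were DSCAM-AS1 (279-fold), the sulfatase gene SULF2 (267-fold), the tight junction gene CLDN3 (209-fold), CDH1 (165-fold), the oestrogen-induced TFF1 (150-fold), CA2 (135-fold), IGFBP2 (103-fold) and AGR3 (103-fold). The oestrogen receptor programme had a median of -3.10 in this pair, below all 10000 random lists, with 15 of its 20 genes at least 2-fold lower.

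In the ovarian pair 428 genes were at least 4-fold higher and 809 at least 4-fold lower in SKOV3 than in OVCAR3, of 10489. Higher in SKOV3 were the calcium-binding CALB1 (332-fold), osteopontin, SPP1 (131-fold), SPANXB1 (114-fold), the tryptophan-degrading IDO1 (109-fold), GPX1 (107-fold, with 10.4 in OVCAR3), PPP1R1B (105-fold), PDZK1IP1 (99-fold) and the clotting inhibitor TFPI (75.6-fold). Lower were the cell cycle inhibitor CDKN2A (223-fold), NPR3 (134-fold), the activin-binding FST (101-fold), the kallikrein KLK10 (90.7-fold), CCDC144NL-AS1 (88.4-fold), FLG (84.7-fold), PPP1R14A (71.4-fold) and RAB25 (70.1-fold). The median over all tested genes was -0.09 in this pair, and 34.6% of the genes at 4-fold were higher. Quantile normalization within the set moved that median to 0.02 and the counts to 504 higher and 640 lower, or 44.1% higher. The ovarian and Mullerian epithelium list had a median of -1.59 in this pair, below all random lists. Its members KLK5, KLK8 and KLK10, bright in OVCAR3 alone, were not tested and did not enter this median.

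In the melanoma pair 826 genes were at least 4-fold higher and 797 at least 4-fold lower in C8161 than in MUM2C, of 10848. The pigment cell genes MLANA (439-fold), TYRP1 (376-fold) and PMEL (319-fold) were lower in C8161, as were ERBB3 (227-fold), QPCT (190-fold), and the tumour antigen genes MAGEA6 (181-fold), MAGEA12 (147-fold) and PRAME (119-fold). The melanocytic list had a median of -4.43 in this pair, below all random lists, with 14 of 16 tested genes at least 2-fold lower. Its members MLANA, TYR, SOX10 and S100B, bright in MUM2C alone, were not tested and did not enter this median. Higher in C8161 were the interleukin receptor IL13RA2 (439-fold), the actin-binding TMSB4X (407-fold, with 57.6 in MUM2C), BASP1 (348-fold), KRT7 (340-fold), PLAC8 (282-fold), C19orf33 (270-fold), CXCL1 (269-fold) and the aminotransferase BCAT1 (228-fold). The beta-actin 3' to 5' ratio of 3.58 on the C8161 array against 1.14 on the MUM2C array applies to each value of this pair. MAGEA6 and MAGEA12 are near-identical family members whose probe sets can share signal.

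In the prostate set 338 genes were at least 4-fold higher and 209 at least 4-fold lower in both DU145 and PC3 than in LNCaP. DU145 alone had 621 higher and 402 lower, and PC3 had 727 and 462. The caveolin CAV1 was 194-fold higher in DU145 and 180-fold higher in PC3, with a scaled signal of 27.4 in LNCaP. S100A6 (176-fold and 113-fold) and the Wnt inhibitor DKK1 (101-fold and 222-fold) were higher too, with CTHRC1 (113-fold and 96.7-fold), ANXA2 (84.2-fold and 88.4-fold), MYOF (119-fold and 83.6-fold), EDIL3 (210-fold and 82.1-fold) and the spectrin gene SPTBN1 (74.0-fold and 75.8-fold). Lower in both were the androgen-glucuronidating UGT2B15 (113-fold and 102-fold) and UGT2B17 (72.6-fold and 72.7-fold), the peptidase MME (98.6-fold and 93.0-fold), MAGEA6 (97.9-fold and 92.6-fold) and MAGEA12 (69.4-fold and 59.1-fold). Also lower were FOLH1B (57.0-fold and 51.7-fold), GLYATL1 (41.8-fold and 42.0-fold) and PRUNE2 (41.2-fold and 71.2-fold). The probe sets of UGT2B15, FOLH1B and ANXA2 can share signal with near-identical genes. The androgen receptor programme had a median of -1.76 in DU145 and -0.91 in PC3 over its tested genes. Its members KLK2, FOLH1, UGT2B15 and UGT2B17, bright in LNCaP alone, were not tested and did not enter these medians. The androgen receptor gene itself had no single-gene probe set in the annotation given and was not analysed here.

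**Figure D4:**
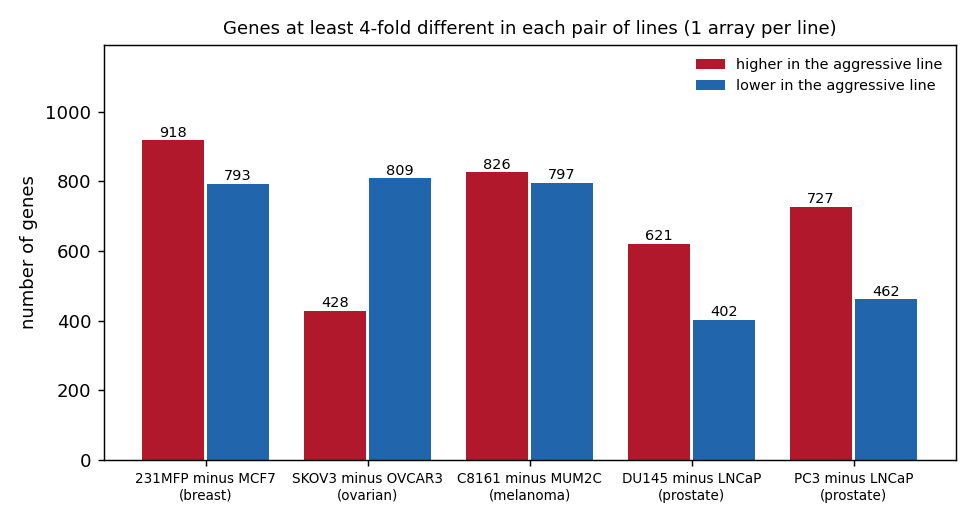
Number of genes (vertical axis) at least 4-fold higher (red) or lower (blue) in the aggressive line of each pair, from 1 array per line. The ovarian pair has 428 higher and 809 lower genes, whereas both prostate pairs have more higher than lower genes.

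Differences were compared between sets across the 12137 tested genes, which are not independent replicates. Pearson's r between pairs of different sets lay between 0.055 (SKOV3 and PC3) and 0.287 (231MFP and PC3). DU145 and PC3, compared with the same LNCaP array, had r = 0.645 and a covariance of 0.939. Unchanged lines simulated against a shared line gave r = 0.502 and a covariance of 0.711. Their noise was the residual spread between lines over all sets, so this covariance is no baseline for the prostate arrays alone. On the same prostate arrays, r was 0.364 with DU145 as the shared line (covariance 0.434) and 0.477 with PC3 as the shared line (covariance 0.603). Both prostate lines had 338 genes at 4-fold or more higher among 11094, where independent lists would share 25.6, and part of this excess may come from the shared array. 231MFP and PC3 shared 272 higher genes, where independent lists would share 43.2. SKOV3 and PC3 shared 85 higher genes, where independent lists would share 19.2. Genes at 4-fold or more in opposite directions also exceeded independent lists in each of the 9 comparisons between sets. They ran from 57 against 52.6 (231MFP and DU145) to 108 against 45.0 (SKOV3 and PC3), and were 69 against 62.2 for 231MFP and PC3 and 116 against 74.9 for 231MFP and C8161.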

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

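The tests of splits and of class assignments, of growth medium and of cells of another line were chosen only after the results they bear on had been seen. Dixon's test was run on 38 groups of values, and chance flags about 1 group in 20. It marked 2, both on C8161. The log2 beta-actin 3' to 5' ratio of C8161 stood apart from the other aggressive lines (0.788 of the range), and so did its GAPDH ratio (0.848 of the range). Some lists lay outside the middle 95% of random lists in opposite directions in different sets. These differences between sets were not tested. The epithelial list had medians of 0.687 (C8161), -3.06 (231MFP), -1.2 (SKOV3), -0.866 (DU145) and -0.753 (PC3). The cholesterol synthesis list was at 0.831 in SKOV3 and -1.06 in 231MFP. The ovarian and Mullerian epithelium list was at 1.59 in C8161 and -1.59 in SKOV3. TGF beta signalling was at 0.574 in DU145, 1.23 in PC3 and -1.35 in SKOV3.

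For the 7 genes past the adjusted threshold, 100 of the 126 splits of the 9 arrays into 5 and 4 were drawn, and 98 of them could be fitted. Of these 98, 3 gave as many genes, the labelled split included. The highest other split gave 13. It occurred in 2 splits that are mirror images of each other within the sets, with both ovarian lines together and the 3 prostate lines together, so that only the breast and melanoma pairs carried the contrast. Of the 24 assignments of class within the sets, 1 gave as many as 7, which was the labelled assignment, and the highest other gave 1. The share of 1 of 24 is under 0.05 but is the smallest that these assignments can give. Since the test was chosen after the 7 genes were seen, chance is not excluded by it. Among the drawn splits the share was under 0.05 too, but the other 26 splits were not fitted, and the share over all of them is not known.

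The count of 96 genes at 2-fold or more in the same direction in all 5 pairs was weighed first. Among the 24 assignments only the labelled one, 1 of 24, gave as many, and the highest other gave 62. That share is the smallest the 24 assignments can give, and the test was chosen after the count was seen. Chance assignment is therefore not excluded by it. Probe sets without a single named gene held 6 at 2-fold or more in all 5 pairs, where other assignments reached 13. Scaling of the arrays is argued against, since 90.62% of the genes stayed at 2-fold in all 5 pairs after quantile normalization of all arrays. RNA quality stays open. The beta-actin ratio was higher in the aggressive line in 3 of the 5 pairs, but in the prostate pairs it was lower by less than the 0.2 log2 set as the bound. The difference in class between the lines is the biological explanation the design names, and it remains a hypothesis.

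The mesenchymal list, higher in the aggressive line of all 5 pairs, was weighed next. Growth medium is argued against as its whole cause, since the list's median was still at least 1.36 higher in the ovarian and melanoma pairs, whose lines shared a medium. Fibroblasts in the aggressive cultures are argued against too. In each aggressive line at least 3 of the 5 abundant fibroblast genes COL1A1, COL1A2, COL3A1, DCN and LUM had a scaled signal under 200. DCN was at 109 or less in every aggressive line, whereas VIM reached 19850 or more. Other markers were brighter in some lines, with COL1A2 at 1825 in SKOV3 and COL1A1 at 1672 in PC3 and 568 in C8161. Outside those 5 genes, COL6A3 was at 4657 in PC3, 873 in 231MFP and 848 in C8161, and FAP at 410 in C8161. COL6A3 was at 69.6 or less in SKOV3 and DU145, and PDGFRB, POSTN and THY1 were at 201.1 or less in every aggressive line. In 231MFP COL1A1 was at 207 and LUM at 241, so that line just met the bound of 3 genes under 200. Medium in the breast and prostate pairs was not separated from the class. The class itself may account for the pattern, as a hypothesis found and tested on the same arrays.

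The third pattern was that epithelial genes were higher in C8161 than in MUM2C, against their direction in the other sets. Cells of MCF7, OVCAR3 or SKOV3 in the C8161 culture are argued against. The share of such a line's epithelial signal found in C8161 differed by at least 253.2-fold between the 10th and the 90th percentile of the genes. This sets levels of different sets against each other, on arrays that were all processed with MAS5. For 231MFP, added later with 9 genes, the share differed by 3943-fold. For the prostate lines LNCaP, PC3 and DU145 (added later) it differed by 390.5-fold, 679.7-fold and 1173-fold, over 22, 17 and 13 genes. These shares also carry the difference between RMA and MAS5. The 10th and 90th percentiles were 0.315% and 123% for LNCaP, 0.435% and 296% for PC3, and 0.144% and 169% for DU145. A mixture would leave about the same share for each gene. Cells of these lines are therefore argued against as the whole cause, for those genes. The list's median depends on values near the floor, falling from 0.687 to 0.23 with a pseudocount of 200 and to 0.03 with a floor of 100. Values near the floor therefore stay open for the list as a whole, where 6 members at 4-fold or more reached a scaled signal of 1000 in C8161, fewer than the 10 set as the bound. Those 6 were KRT7, KRT8, KRT18, DSP, SPINT2 and AP1M2, with KRT8 at 16850 in C8161 and 73.5 in MUM2C. The 3' to 5' ratio of 3.58 on the C8161 array was not separated from this pattern, and a difference between the 2 lines remains an untested biological explanation.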

How the results depend on the processing

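The 7 genes that passed across the sets were called again with the values as deposited, quantile normalization within sets, the stricter filter and the trended prior. The count moved to 2 with a pseudocount of 16, 3 with a floor of 100, 4 with quantile normalization of all arrays, 1 without a filter, 13 without the set block (all 7 included) and 2 with 1 difference per set. Leaving out 1 line at a time it lay between 0 and 4, with at most 2 of the 7 genes among them. The cause was not tested, beyond the loss of a set's difference from the fit. SLCO1B3 passed under all 12 other settings and 5 of the 9 leave-outs (adjusted p up to 0.0916), whereas NCEH1, LOXL2, ZEB1 and IGFBP6 passed in 0 of the 9. Over all alternatives the adjusted p of NCEH1 ran from 0.0095 to 0.177, that of LOXL2 from 0.0235 to 0.212, and that of ZEB1 from 0.0306 to 0.165. The 7 genes kept their direction throughout, but not their size. The log2 difference ran from 1.72 to 4.85 for LOXL2, 2.30 to 5.38 for ZEB1, 3.38 to 6.19 for SLCO1B3, 3.48 to 5.61 for CDA and -5.92 to -2.79 for ZNF595.

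The mesenchymal list kept its direction and its camera call under all 21 alternatives (mean 1.54 to 2.47), and so did the epithelial list (-1.71 to -0.47), all at the preset correlation. With an estimated correlation both lost the call (adjusted p = 0.10 and 0.518). The stem and progenitor list lost its call without a filter (0.327) and without LNCaP, and its leave-out means ran from 0.316 to 1.04. The endocannabinoid list never passed, with leave-out means from -0.038 to 0.2, below 0 without the ovarian pair. CD24, which never passed, ran from -0.58 to 2.54 on leave-out, at -0.20 without the melanoma pair and -0.58 without LNCaP.

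The genes at 2-fold in all 5 pairs were 38 lower with a pseudocount of 16, 10 lower with 200 and 39 higher with the mean of all probe sets. With a line left out, and so fewer pairs to meet, they were 92 to 196 higher and 34 to 157 lower. A pseudocount of 200, which shrinks differences of dim genes, reduced the counts at 4-fold (higher and lower) to 511 and 405 in the breast, 252 and 308 in the ovarian and 461 and 407 in the melanoma pair, 377 and 222 in DU145, 466 and 255 in PC3, and 179 and 115 in both prostate lines. The mean of all probe sets gave 260 higher in the ovarian and 502 higher in the melanoma pair, 400 and 257 in DU145, 480 and 297 in PC3, and 214 higher in both. Quantile normalization of all arrays gave 527 lower in the ovarian pair. The cause was not tested. Other genes named outside the lists, and medians of the 4 main lists outside the range of random lists, kept their direction in each pair under the pseudocount, scaling and probe set alternatives. The epithelial median of the melanoma pair kept it only narrowly, at 0.23 with a pseudocount of 200 and 0.03 with a floor of 100. Signals near the array background limit the folds of dim genes, and 1 array per line limits all of them.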

Other observations

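Only the test on PHGDH below bears on a hypothesis, and its bounds were set before it was run. Several lists outside the comparisons above passed camera at the preset correlation and not with an estimated correlation. The MHC list was higher by a mean of 0.52 with 11 of 13 genes higher (adjusted p = 0.0091; adjusted p = 0.518 with an estimated correlation), led by HLA-B (1.36 ± 0.55) and HLA-C (1.02 ± 0.35), with HLA-DMA (-0.66 ± 0.76) and HLA-DQB1 (-0.32 ± 0.41) lowest. Integrins and adhesion genes were higher by 0.53 with 14 of 20 genes higher (adjusted p = 0.0104; adjusted p = 0.42 with an estimated correlation), led by ITGA3 (2.84 ± 0.66) and ALCAM (2.28 ± 0.62), with NRCAM (-2.25 ± 0.74) and ITGB3 (-1.43 ± 1.0) lowest. The hypoxia list was higher by 0.42 with 14 of 20 genes higher (adjusted p = 0.0104; adjusted p = 0.42 with an estimated correlation), with LOX at 2.72 ± 0.88, ADM at 1.97 ± 0.79, EGLN3 at -1.30 ± 0.59 and DDIT4 at -1.08 ± 0.93. Glycolysis was higher by 0.29 with 13 of 22 genes higher (adjusted p = 0.0341; adjusted p = 0.42 with an estimated correlation). The glucose transporter SLC2A1 (1.62 ± 0.33), the only member past the list-alone adjustment, and LDHB (1.25 ± 1.04) were highest, and PFKFB4 (-0.96 ± 0.92) and ALDOC (-0.63 ± 0.58) lowest.

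The oestrogen receptor programme was at a mean of -0.51 with 14 of 20 genes lower (adjusted p = 0.0385; adjusted p = 0.592 with an estimated correlation). Its medians were -3.10 in the breast pair and between -0.47 and 0.52 in the others. GREB1 (-3.33 ± 0.66) and MYB (-1.72 ± 0.66) were lowest, and SERPINA1 (2.36 ± 1.0) and IGFBP4 (2.14 ± 1.58) highest. The melanocytic list was at -1.04 with 11 of 16 genes lower (adjusted p = 0.0302; adjusted p = 0.592 with an estimated correlation), with GPR143 at -2.86 ± 0.85 beside ERBB3, and RAB38 at 1.41 ± 1.11 and BCL2A1 at 1.36 ± 0.99. The androgen receptor programme (adjusted p = 0.319, 11 of 16 genes lower), cholesterol synthesis (adjusted p = 0.292, 12 of 17 lower), TGF beta signalling (adjusted p = 0.631, 13 of 26 lower) and ovarian and Mullerian epithelium (adjusted p = 0.606, 6 of 14 lower) did not pass. In the last list the mean was -0.06, the median 0.07 and the test's direction up, and the transcription factor MECOM (2.71 ± 0.35) passed over the list alone. Among the control lists, LAPTM5 was 2.94 ± 0.88 higher across the sets without passing over all genes (adjusted p = 0.339). It passed over its list alone, in which 2 genes were tested (adjusted p = 0.0218), and was lower in DU145 (-0.26) and PC3 (-0.37) than in LNCaP. Of the endothelial genes, TIE1 was 5.29, ENG 3.28 and CDH5 3.22 higher in C8161 than in MUM2C, and ESAM was 3.81 higher in 231MFP than in MCF7.

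Some genes were near 0 in a line while bright in most of the others, and the sequence under their probes was not examined. They were picked after their values were seen. GPX1 had a scaled signal of 10.5 in MCF7 and 10.4 in OVCAR3 against at least 6408 in the other lines, and TMSB4X 57.6 in MUM2C against at least 2787 in the others, across sets processed with MAS5 and with RMA. Other named genes showed this too, such as PLS3 with 20.3 in MCF7 against at least 4171 in the others. In LNCaP, CAV1 was at 27.4, S100A6 at 58.2 and SPTBN1 at 68.1, against at least 5576, 2448 and 5558 in the others. Probe sets without a single named gene held 6 of 3172 at 2-fold or more in all 5 pairs, where other assignments of class reached 13.

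PHGDH was lower in the aggressive line of all 5 pairs, by 4.33-fold in 231MFP, 29.3-fold in SKOV3, 3.45-fold in C8161, 2.76-fold in DU145 and 2.67-fold in PC3, without passing across the sets (adjusted p = 0.243). A hypothesis was that the genes of serine synthesis and its folate branch move with PHGDH. The median of PSAT1, PSPH, SHMT1, SHMT2 and MTHFD2 was under -0.5 in 1 of the 5 pairs, PC3 (-0.79), and 0.86 in C8161. These 5 genes, of serine synthesis and its folate branch, therefore did not move with PHGDH as a group. SHMT1 was too dim to be tested across the sets, and it gave the median in SKOV3 (-0.36) and DU145 (0.05).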
